A study of Homo sapiens with 8 samples.

How the data were processed

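H3K27ac, a histone mark found at active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing with the Abcam antibody ab4729 in clonal lines of CFPAC1, an established human pancreatic ductal adenocarcinoma cell line. Control clones 1 and 4 carried the lentiCRISPRv2 plasmid as the labels describe it for controls, with no guide named. IRF1-guide clones 11 and 13 carried the plasmid with Cas9 and a guide RNA against IRF1, an interferon-regulated transcription factor. Each of the 4 clones gave 1 library without treatment (UT in the labels) and 1 library after 2 hours of hIFNb, read here as human interferon beta, so that each of the 4 groups held 2 libraries and the 8 libraries made 4 pairs by clone number. The labels state what the guide targets and not whether a clone lacks the IRF1 protein, and H3K27ac at the IRF1 gene does not measure it. The clone names are therefore used only as names for what each clone carried.

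Per the submitters' processing notes, reads were aligned with Bowtie2 to GRCh38 (hg38). The version of Bowtie2, the peak caller, the merging of peaks, the read counter and the scaling method are not given in the sources used here. The deposited table holds 1 score per peak and library for 31961 peaks, which the authors normalised by a method not stated and rounded to whole numbers. In the columns other than those of the control clones without hIFNb, from 10 to 30 of the whole numbers up to 100 are never used, as rounded products of read counts and a single factor per library would leave them. The columns of the control clones without hIFNb have no such gaps, and their factors rest on a much smaller gain in likelihood (131.6 and 49, against at least 3188.9 in the others). The inferred factors ran from 0.982 to 1.42. They placed the reads in peaks between 2332989 in IRF1-guide clone 13 without hIFNb and 3471255 in control clone 1 without hIFNb. The totals of the deposited scores ran from 3277561 to 3460390. These inferred depths are estimates, and the depth outside peaks is unknown. Peak coordinates and the distances to the transcription start sites (TSS) named by the authors came from the same deposited table. Peaks covered 190.6 Mb in all, with a median width of 3550 bp, and 9903 peaks (31%) held a TSS by the authors' annotation.

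Scores were analysed as log2(score + 1). Requiring a score above 0 in at least 2 libraries removed no peak. Each comparison was a contrast in a group-means model of the 8 libraries in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation, a mean-variance trend and Benjamini-Hochberg adjustment over the 31961 peaks. A peak was called at an adjusted p under 0.05. The contrasts were the hIFNb response averaged over all clones, in control clones and in IRF1-guide clones, the difference between the latter pair of responses, and the difference between IRF1-guide and control clones without and with hIFNb. The difference between genotypes over both treatments was tested on clone means, 2 clones against 2. Errors printed beside log2 changes are standard errors (SE) from these fits, and errors beside scores are standard deviations (SD) of 2 clones. The replicates are clones, so the p-values of the group-means model measure the spread between libraries of different clones. That model takes the 2 libraries of a clone as independent, while the test on clone means counts each clone once. Peaks were also tested with the clone as a block, which compares the libraries of each clone with each other. The pairing by clone number was checked in the scores, where the deviations of a clone's 2 libraries from their group means correlated across peaks at 0.437 in control clones and 0.392 in IRF1-guide clones.

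A peak was linked to the protein-coding gene whose TSS lay nearest to its centre within 50 kb, and was called a promoter peak when that TSS lay inside it or within 2 kb. This linked 19195 peaks to 10968 genes, with 8780 promoter peaks. TSS positions were rebuilt from the distances in the deposited table for 12167 genes, of which 10545 fell exactly on a RefSeq gene end, and 1780 more genes had a TSS named inside a peak. Of the 29099 TSS names in the table, 27255 (93.7%) matched a RefSeq symbol. A link is a statement of distance and does not show that a peak acts on that gene. Gene bodies came from RefSeq on GRCh38.

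The comparisons, the tests, 16 gene lists and the rule for naming genes were fixed before the data were examined. The rule took, from each comparison with calls, up to 12 rises and 12 falls with the largest log2 change among called peaks whose libraries did not overlap between the groups, 1 per gene, and up to 4 genes per list. IRF1, IRF9, ISG15, GAPDH and ACTB were always named, and a comparison without calls was described by the peaks of smallest p, said not to pass. Any other gene is said to have been chosen after its values were seen. Some genes that the rule takes are not reported here. The lists were interferon-stimulated genes, antigen processing and MHC, guanylate-binding, APOL and other interferon-gamma-type genes (here the GBP and APOL list), cholesterol biosynthesis, fatty acid and glycerolipid synthesis, lipid transport and oxidation, glycolysis, the TCA cycle and respiratory chain, amino acid synthesis and ATF4 targets, xenobiotic, steroid and retinoid metabolism, low-grade (classical) epithelial genes, high-grade (basal or mesenchymal) genes, NF-kB and inflammatory genes, cell cycle genes, markers of other cell types, and housekeeping genes. They held 477 genes, of which 360 had a linked peak. Lists were tested with camera in limma at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the 16 lists of a comparison.

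The fits were tested on simulated data with a clone SD of 0.242 and a library SD of 0.143 on the log2 scale and 100 changed peaks of each size. Both SDs were taken from peaks with a mean score of at least 100. The changed peaks were drawn from those with a mean of at least 20, so recovery at lower scores was not measured. They were a small part of all peaks. The adjustment depends on how many peaks change, so recovery may differ where many do. Averaged over all clones, 53% of changes of 1 on the log2 scale and 100% of changes of 2 were recovered. Within a single genotype 5% of changes of 1 were recovered, with 82% of changes of 2 in control clones and 85% in IRF1-guide clones. For a response in control clones alone, the difference between responses recovered 0% of changes of 1 and 30% of changes of 2, or 22% and 90% with the clone as a block. Differences between genotypes of 1 and 2 were recovered at 9% and 86% without hIFNb, 14% and 85% with hIFNb, and 31% and 100% on clone means.

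Alternatives changed 1 choice at a time: a pseudocount of 10, a minimum mean score of 20, median-of-ratios and quantile scaling, robust moderation, no variance trend, a minimum log2 change of 1, the clone as a block, the 4 compared libraries alone, centring on 10 Mb windows, other treatments of the clone in the comparison over both treatments, promoter peaks or links within 200 kb for the lists, and leaving out each library or clone in turn. Voom on the inferred reads, a block by the R1 or R2 ending of the column names and linking a peak to every gene with a TSS inside it were chosen after seeing the data. Tests that need deposited read counts were not run, because the deposited values are normalised, and motifs were not searched, because no genome sequence was at hand. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.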

Results

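The data comprised 8 H3K27ac libraries from 4 clonal lines of CFPAC1, with 2 control clones (1 and 4) and 2 IRF1-guide clones (11 and 13), each untreated and after 2 hours of hIFNb. The series title concerns IRF1 and metabolism in low-grade pancreatic cancer. The comparisons ask where H3K27ac changed with hIFNb, and where IRF1-guide clones differed from control clones. Values are scores, the deposited normalised peak counts. Their totals per library were 3408527 and 3414984 in control clones 1 and 4 without hIFNb, 3410393 and 3460390 in the same clones with hIFNb, 3317881 and 3316085 in IRF1-guide clones 11 and 13 without hIFNb, and 3278918 and 3277561 with hIFNb. The inferred reads in peaks behind them ran from 2332989 to 3471255, and the median peak had a mean score of 47.4. In a principal component analysis of the log2 scores, the first component held 40.5% of the variance and the second 21.5%. On the first component the control clones with hIFNb lay at 98 and 86.1, the IRF1-guide clones with hIFNb at 7.9 and -19, the control clones without hIFNb at -8.4 and -17.5, and the IRF1-guide clones without hIFNb at -65.2 and -81.9.

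Interferon-stimulated genes gained H3K27ac within 2 hours of hIFNb in all 4 clones. At the promoter of RSAD2, which encodes the antiviral protein viperin (chromosome 2, 6863716 to 6878834), the mean score went from 44 ± 18.4 to 391.5 ± 6.4 in control clones and from 18 ± 1.4 to 275 ± 9.9 in IRF1-guide clones (SD, n = 2 each). This was a rise of 3.52 ± 0.20 on the log2 scale over all clones (SE, limma, adjusted p = 2.59e-05). The promoter of HERC6, an interferon-induced HECT-type ubiquitin ligase gene, rose by 2.99 ± 0.18 (adjusted p = 2.77e-05). The promoter of CXCL10, a chemokine gene whose product attracts T cells, rose by 2.87 ± 0.24 (adjusted p = 0.000141), and that of HERC5 by 2.88 ± 0.35 (adjusted p = 0.000848). IRF9, an interferon regulatory factor gene, rose by 1.34 ± 0.16 (adjusted p = 0.000695), and ISG15, which encodes a ubiquitin-like modifier, by 1.13 ± 0.14 (adjusted p = 0.000956). Of the 99 peaks linked to 56 genes of the interferon-stimulated list, 60 rose, 4 fell and 35 did not pass the test, and adjusted over the list alone 71 rose and 7 fell. The list had a median log2 change of 1.08 and a camera adjusted p of 7.10e-28 (adjusted p = 0.0105 with an estimated correlation). GAPDH changed by 0.07 ± 0.12 (adjusted p = 0.777) and ACTB by 0.15 ± 0.19 (adjusted p = 0.671), without passing, and of the 16 peaks of the housekeeping list limma called none in the group-means model and 2 rises with the clone as a block.

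**Figure D1:**
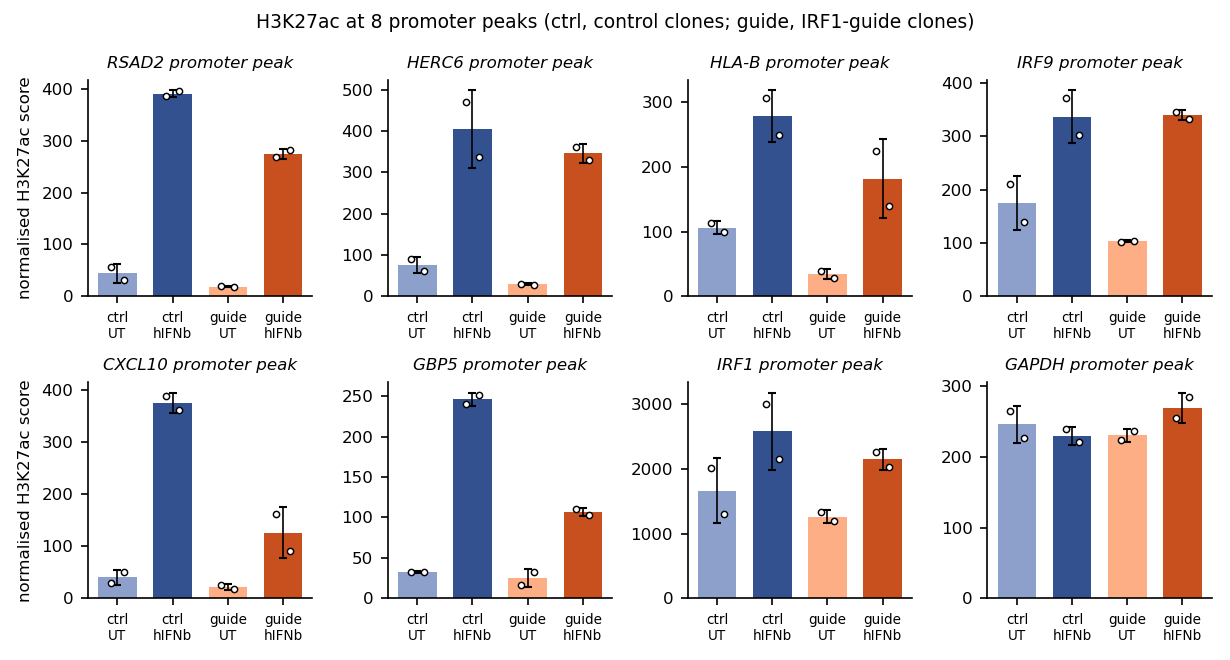
H3K27ac scores (normalised peak counts, y axis from 0) of 8 promoter peaks in the 4 groups; bars are means, error bars are SD and points are the 2 clones of a group. RSAD2 reached 391.5 in control clones and 275 in IRF1-guide clones with hIFNb, CXCL10 reached 375 and 126, and GAPDH stayed between 230 and 270 in all 4 groups.

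Other immune gene groups also rose with hIFNb. Promoters of the classical and non-classical MHC class I genes, whose products present peptides to T and natural killer cells, rose by 2.18 ± 0.23 at HLA-F (limma, adjusted p = 0.000419), 1.93 ± 0.15 at HLA-E (adjusted p = 0.000103), 1.88 ± 0.20 at HLA-B (adjusted p = 0.000363) and 1.81 ± 0.15 at HLA-C (adjusted p = 0.000137). Of 43 peaks of the antigen processing and MHC list, 15 rose and none fell, or 20 rose and 1 fell adjusted over the list alone, with a camera adjusted p of 5.60e-09 (adjusted p = 0.0804 with an estimated correlation). In the GBP and APOL list 21 of 41 peaks rose and 2 fell, or 26 and 2 adjusted over the list alone, with a median of 0.81 and a camera adjusted p of 2.44e-13 (adjusted p = 0.0105 with an estimated correlation). GBP5, a guanylate-binding GTPase gene of cell-autonomous immunity, rose by 2.50 ± 0.21 at its promoter (adjusted p = 0.000143). SOCS1, which encodes a feedback inhibitor of cytokine signalling, rose by 2.31 ± 0.19 (adjusted p = 0.000115), and the complement-pathway genes C1S and SERPING1 by 2.69 ± 0.38 and 2.88 ± 0.51 (adjusted p = 0.00196 and 0.007). The type III interferon genes were among the largest rises, with 4.13 ± 0.38 at IFNL2 (adjusted p = 0.000212) and 3.94 ± 0.35 at IFNL3 (adjusted p = 0.000164). The mean score at IFNL2 went from 3 ± 2.8 to 125 ± 53.7 in control clones and from 4.5 ± 0.7 to 48.5 ± 14.8 in IRF1-guide clones. At IFNL1 the IRF1-guide clones were listed at 0 without hIFNb, and at 15.5 ± 7.8 with it. The largest rise among called peaks was 4.93 ± 0.29 in the body of LINGO1, at chromosome 15, 77609005 to 77617295 (adjusted p = 2.77e-05), and a peak inside SNX20 rose by 3.83 ± 0.21 (adjusted p = 2.59e-05).

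Falls were smaller, and some lay inside interferon-stimulated genes. A peak in the body of RIGI, which encodes a sensor of viral RNA, fell by 2.07 on the log2 scale (SE 0.27, limma, adjusted p = 0.00136), and a peak in DDX60L fell by 1.94 (SE 0.16, adjusted p = 0.000143). A peak linked to FOXA1, a pioneer factor of endodermal epithelium, fell by 1.30 (SE 0.22, adjusted p = 0.0051). Over all clones 2094 peaks rose and 824 fell, 2918 (9.13%) of 31961, with a median absolute change of 1.06 among them. With the clone as a block 5295 rose and 5068 fell, including all 2918. A block by column ending gave 5181 calls, and a minimum log2 change of 1 gave 1586. In 2023 of the 2918 the 4 hIFNb libraries did not overlap the 4 others, against 12.4% of all peaks. Of promoter peaks 486 of 8780 rose and 29 fell, and of all other peaks 1608 of 23181 rose and 795 fell. The count fell to 1426 without control clone 1 with hIFNb, 1497 without IRF1-guide clone 11 with hIFNb, 1532 and 1752 without control clones 1 and 4 without hIFNb, 1732 without IRF1-guide clone 11 without hIFNb and 1865 without control clone 4 with hIFNb. The RIGI, DDX60L and FOXA1 calls held with each library left out in turn.

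Metabolic gene lists, the subject of the series title, differed in how many peaks were called after 2 hours of hIFNb. Most held more calls with the clone as a block than in the group-means model. So did all 31961 peaks, with 10363 calls against 2918 (9.13%). The counts below are those of the group-means model unless the block is named. In cholesterol biosynthesis 1 of 24 peaks rose, the promoter of IDI1, isopentenyl diphosphate isomerase, which it shares with WDR37 (0.84 ± 0.19, limma, adjusted p = 0.0214). In glycolysis 2 of 23 rose, at HK2, which encodes a hexokinase, an enzyme that phosphorylates glucose (0.51 ± 0.11, adjusted p = 0.0202), and PGAM1 (0.69 ± 0.14, adjusted p = 0.0157), while the list had a median of -0.11. In the TCA cycle and respiratory chain 1 of 39 rose, at the promoter of SDHA, a subunit of succinate dehydrogenase (0.76 ± 0.16, adjusted p = 0.0146). In fatty acid and glycerolipid synthesis 2 of 52 rose, at ELOVL1 and at a peak of low score linked to ACSL4. In lipid transport and oxidation 1 of 40 peaks fell and none rose. None of the 25 peaks of amino acid synthesis and ATF4 targets was called in this model. In xenobiotic, steroid and retinoid metabolism 3 of 38 rose and 3 fell: the promoter of CYP1A1, an aryl hydrocarbon receptor target, rose by 2.85 ± 0.27 (adjusted p = 0.000238) with CYP2J2, and peaks linked to AHR and ALDH1A1 fell. CYP1B1, which also rose, was chosen after its values were seen. Adjusted over the list alone the counts were the same in these lists, except fatty acid synthesis, with 0. With the clone as a block 5 glycolysis peaks rose and 7 fell, 10 and 3 in the TCA cycle, 4 and 15 in xenobiotic metabolism, 5 and 6 in lipid transport, 5 and 5 in fatty acid synthesis, 5 and 1 in amino acid synthesis, and 1 and 0 in cholesterol biosynthesis. The camera adjusted p was 0.862 for cholesterol biosynthesis, 0.825 for fatty acid synthesis, 0.844 for lipid transport, 0.529 for glycolysis, 0.053 for the TCA cycle, 0.289 for amino acid synthesis and 0.34 for xenobiotic metabolism. Fry, which asks whether a list's peaks moved one way on balance, passed upward for the TCA cycle (adjusted p = 0.00463), amino acid synthesis (0.0232) and fatty acid synthesis (0.0457) and downward for glycolysis (0.0327). It did not pass for cholesterol biosynthesis (0.342), lipid transport (0.761) or xenobiotic metabolism (0.761). The CYP1A1 and CYP2J2 calls held with each library left out in turn. Without control clone 1 without hIFNb the adjusted p was 0.082 at IDI1, 0.0632 at PGAM1, 0.115 at AHR and 0.0543 at ALDH1A1. Without control clone 4 without hIFNb it was 0.0762 at HK2 and 0.0508 at SDHA. Without control clone 1 with hIFNb it was 0.0622 at IDI1, 0.0584 at PGAM1, 0.0781 at HK2 and 0.0635 at SDHA. Without control clone 4 with hIFNb it was 0.0647 at IDI1 and 0.0862 at AHR. Without IRF1-guide clone 11 without hIFNb it was 0.0689 at IDI1 and 0.0745 at AHR, and without clone 13 without hIFNb 0.0506 at PGAM1, 0.0634 at HK2 and 0.0859 at AHR. Without clone 11 with hIFNb it was 0.0834 at IDI1, 0.0654 at PGAM1, 0.0733 at HK2, 0.112 at AHR and 0.052 at ALDH1A1. Without clone 13 with hIFNb it was 0.0509 at SDHA. The ELOVL1 and ACSL4 calls were lost whichever of the 8 libraries was left out (0.059 to 0.139 and 0.06 to 0.136).

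Among epithelial and other programmes, 5 of 81 low-grade epithelial peaks fell and 1 rose (4 and 1 adjusted over the list alone). The falls were linked to FOXA1, to TSPAN8 (2 peaks), to SOX9, a ductal transcription factor, and to CDH17, chosen after its values were seen, and the rise to MUC13. The list's median was -0.11 (camera adjusted p = 0.053, fry, downward, 0.0491), and with the clone as a block 25 of its peaks fell and 9 rose. In the high-grade list a peak linked to SNAI1, a repressor of epithelial genes, rose by 1.03 ± 0.15 (limma, adjusted p = 0.00233) and 1 of 45 fell. Its median was 0.049 although camera pointed down (adjusted p = 0.997, fry, upward, 0.463), and with the block 8 rose and 7 fell. Of 51 NF-kB and inflammatory peaks 4 rose and 1 fell (5 and 1 adjusted over the list alone), with SAA1, an acute-phase protein gene, up by 2.03 ± 0.33 (adjusted p = 0.00441) and a peak linked to IL6 up by 1.10 ± 0.21 (adjusted p = 0.0106). The median of this list was -0.14 and its mean 0.01 (camera, downward, adjusted p = 0.529, fry 0.821), and with the block 11 rose and 15 fell. Of 32 cell cycle peaks 3 rose, including one inside BUB1 by 1.63 ± 0.17 (adjusted p = 0.000364). Their camera adjusted p was 0.289 and that of fry, upward, 0.0327, and with the block 4 rose and 1 fell. Markers of other cell types gave 1 fall of 22 peaks, at LUM (camera adjusted p = 0.862, downward, with a median of 0.009, fry, upward, 0.821), or 4 rises and 5 falls with the block. Housekeeping genes had a camera adjusted p of 0.934 and a fry adjusted p of 0.761. The SOX9 call was lost whichever of the 8 libraries was left out (adjusted p = 0.0593 to 0.14), the TSPAN8 call with each but IRF1-guide clone 13 with hIFNb (0.0667 to 0.135), and the fall at SCEL in the high-grade list with each but IRF1-guide clone 13 without hIFNb (0.0605 to 0.131). The LUM call was lost with each left out but control clone 4 and IRF1-guide clone 13 with hIFNb (0.0584 to 0.108). The MUC13 call was lost without control clone 4 without hIFNb (0.056) or with it (0.0561), or IRF1-guide clone 11 with hIFNb (0.0617).

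In control clones alone immune genes were again among the largest rises. The largest rises linked to a gene were 5.12 ± 0.54 at IFNL2 (limma, adjusted p = 0.00124), 4.89 ± 0.49 at IFNL3 (adjusted p = 0.00108), 4.82 ± 0.56 at a peak linked to ARRDC3 (adjusted p = 0.0019) and 4.51 ± 0.43 at a peak linked to IRF8, another interferon regulatory factor gene (adjusted p = 0.000939). RSAD2 rose by 3.19 ± 0.28, CXCL10 by 3.24 ± 0.34, GBP5 by 2.88 ± 0.30 and HLA-E by 1.67 ± 0.21 (adjusted p = 0.000718, 0.0012, 0.00118 and 0.00275). In the interferon-stimulated list 44 peaks rose and 4 fell (65 and 4 adjusted over the list alone; camera adjusted p = 7.29e-21, adjusted p = 0.0111 with an estimated correlation). In the MHC list 9 rose and none fell (17 and 0 adjusted over the list alone; camera adjusted p = 1.83e-07, adjusted p = 0.112 with an estimated correlation). In the GBP and APOL list 19 rose and none fell (21 and 2 adjusted over the list alone; camera adjusted p = 3.65e-13, adjusted p = 0.0111 with an estimated correlation). The low-grade epithelial list was lower, with a median of -0.19 (camera adjusted p = 0.0128, adjusted p = 0.163 with an estimated correlation), although its only called peak in the group-means model, linked to MUC13, rose, and was lost whichever library was left out (adjusted p = 0.0529 to 0.238). Adjusted over the list alone it had 0 called peaks, and with the clone as a block 4 rose and 24 fell. That list's adjusted p was 0.12 without control clone 1 without hIFNb and 0.212 without control clone 4 with hIFNb. It was 0.0833 with promoter peaks alone and 0.0698 by fry, which passed downward for glycolysis (0.0203) and upward for the TCA cycle (0.0115). In all 1300 peaks rose and 216 fell, or 4271 and 3596 with the clone as a block. All 1516 calls were without overlap, as were 48.7% of all peaks. Leaving out 1 control library brought the count to 206 (clone 1 with hIFNb), 402 (clone 4 with hIFNb), 489 (clone 1 without) and 496 (clone 4 without), the 4 control libraries alone gave 917, and a block by column ending gave 2992.

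In IRF1-guide clones alone several interferon-stimulated genes rose as well. RSAD2 rose by 3.86 ± 0.28 and HERC6 by 3.55 ± 0.25 (limma, adjusted p = 0.000369 for both), SHFL, an antiviral inhibitor of translation, by 3.55 ± 0.39 (adjusted p = 0.00235), and HLA-C by 2.40 ± 0.21 (adjusted p = 0.000938). LAP3, an aminopeptidase gene, rose by 2.31 ± 0.21 (adjusted p = 0.000938). GBP5 rose by 2.12 ± 0.30 at its promoter (adjusted p = 0.00794, or 0.0963 and 0.0644 without clones 11 and 13 with hIFNb). In the interferon-stimulated list 47 peaks rose and 2 fell (63 and 5 adjusted over the list alone; median 1.19, camera adjusted p = 1.97e-37, adjusted p = 0.00708 with an estimated correlation). The MHC list had 8 rises (13 adjusted over the list alone; camera adjusted p = 2.29e-09, adjusted p = 0.0744 with an estimated correlation), and the GBP and APOL list had 8 rises (19 rises and 1 fall adjusted over the list alone; camera adjusted p = 1.87e-11, adjusted p = 0.0142 with an estimated correlation). No other list passed by camera, and fry also passed upward for the TCA cycle (adjusted p = 0.0457) and cell cycle genes (0.0481). The IRF1 gene itself, a broad region of high score (chromosome 5, 132442197 to 132506408), rose by 0.71 ± 0.15 over all clones (adjusted p = 0.0165, and 0.0661 without control clone 1 with hIFNb, 0.056 without IRF1-guide clone 13 without hIFNb and 0.0635 without IRF1-guide clone 11 with hIFNb). Its mean score went from 1660 ± 500.6 to 2581 ± 596.8 in control clones and from 1259.5 ± 102.5 to 2149 ± 164 in IRF1-guide clones (SD, n = 2), which did not pass in either genotype alone (adjusted p = 0.119 and 0.152). That model does not use the pairing by clone. Within clones the score rose from 2014 to 3003 and 1306 to 2159 in control clones 1 and 4, and from 1332 to 2265 and 1187 to 2033 in IRF1-guide clones 11 and 13. In all 383 peaks rose and 8 fell in IRF1-guide clones, or 2379 and 2123 with the clone as a block, the 4 IRF1-guide libraries alone gave 41, and a block by column ending gave 767. All 391 calls were without overlap, as were 42.5% of all peaks. The count was 44 and 122 without clones 11 and 13 with hIFNb, 188 and 233 without clones 11 and 13 without hIFNb, and 260 without control clone 1 with hIFNb.

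The size of the response was then compared between genotypes. At the 2094 risen peaks the median log2 change was 1.485 and 1.408 in control clones 1 and 4, and 1.11 and 0.919 in IRF1-guide clones 11 and 13. Of these peaks 70.1% had a smaller response in IRF1-guide clones, with a median difference of -0.343. At the 581 of them with a mean score of at least 100 the share was 58.5% and the median difference -0.08. The 824 fallen peaks also changed less, with medians of -0.919 and -0.777 in control clones 1 and 4, and -0.706 and -0.567 in IRF1-guide clones 11 and 13. Of these, 72.6% had a smaller response in IRF1-guide clones. The peaks of the interferon-stimulated list went the other way: at its 60 risen peaks the medians were 1.389 and 1.439 in control clones 1 and 4, and 1.853 and 1.585 in IRF1-guide clones 11 and 13. HLA-C, of the antigen processing and MHC list, had a response of 1.23 in control clones and 2.40 in IRF1-guide clones, a difference of 1.17 ± 0.30 (limma, adjusted p = 1). Its mean score went from 97 ± 2.8 to 229 ± 22.6 in control clones and from 32 ± 1.4 to 173.5 ± 24.7 in IRF1-guide clones, so it started and ended lower there. Among the peaks of smallest p, the responses in IRF1-guide clones were smaller at a peak linked to ZDHHC23, -3.62 ± 0.60, and at a peak in KCNIP1, -3.26 ± 0.47, where the score went from 17.5 ± 7.8 to 194 ± 11.3 in control clones and from 28 ± 5.7 to 32 ± 1.4 in IRF1-guide clones (SD, n = 2; adjusted p = 0.599 for both). Neither passed in the group-means model: limma called 0 peaks for the difference between responses, with 1258 at an unadjusted p under 0.05, and voom called 0. At list level the interferon-stimulated list had a larger response in IRF1-guide clones, with a median difference of 0.31 and 0 called peaks (camera adjusted p = 4.65e-05, adjusted p = 0.299 with an estimated correlation). Fry gave this list an adjusted p of 0.0684.

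With the clone as a block 244 peaks differed in response, and 206 of them were not promoter peaks. The log2 change with hIFNb, with its sign, was higher in IRF1-guide clones at 34 and lower at 210, of which 12 and 119 had risen over all clones. Larger log2 rises in IRF1-guide clones included HLA-C (adjusted p = 0.0124) and IRF9 (0.97 and 1.71, adjusted p = 0.0414), and the KCNIP1 peak had a smaller rise (3.46 and 0.20, adjusted p = 6.96e-05). The ZDHHC23-linked peak was also called, with 2.78 in control and -0.84 in IRF1-guide clones (adjusted p = 0.00409). HERC6 (2.42 in control and 3.55 in IRF1-guide clones), MX1, HLA-B and IFIT3, chosen after their values were seen, also rose more on the log2 scale (adjusted p = 0.00663, 0.00663, 0.0255 and 0.0463). The scores of HERC6 and HLA-B had lower means in IRF1-guide clones without and with hIFNb, going from 75 ± 19.8 to 404.5 ± 94 and from 106 ± 9.9 to 278.5 ± 40.3 in control clones, and from 28.5 ± 2.1 to 345.5 ± 21.9 and from 33.5 ± 7.8 to 182 ± 60.8 in IRF1-guide clones (SD, n = 2), so that in score units neither rose more. Blocked camera tests gave the GBP and APOL list a smaller response (adjusted p = 0.0289, adjusted p = 0.434 with an estimated correlation), with medians of 0.93 in control and 0.72 in IRF1-guide clones, which did not pass without the block (adjusted p = 0.0845). Across all 31961 peaks the responses of the genotypes correlated with a Pearson r of 0.593 and a Spearman rho of 0.561, and 71.1% had the same sign. Across the 2918 peaks called for the response averaged over both genotypes, a selection that favours a shared sign, r was 0.822, rho was 0.77 and 99.5% had the same sign. Within these r was 0.453 at rises and 0.29 at falls. Peaks are not independent replicates.

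**Figure D2:**
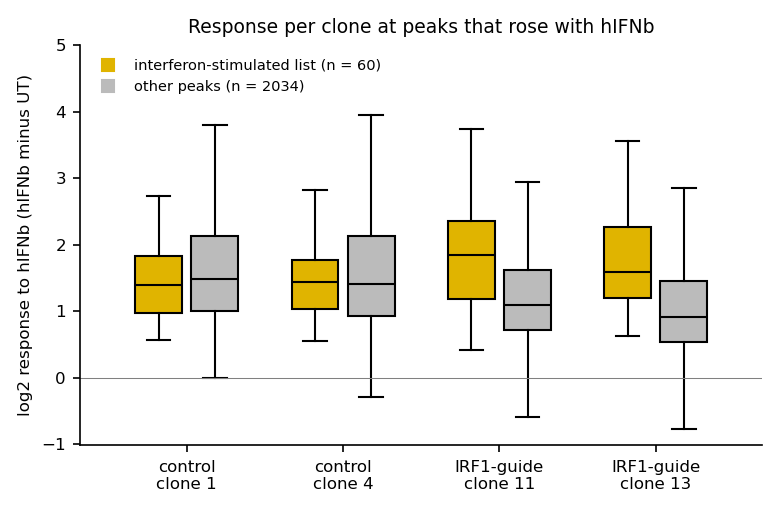
Box plots of the log2 change with hIFNb in each clone (y axis, log2 units; boxes, quartiles; whiskers, 1.5 times the quartile range; outliers not drawn) at the risen peaks of the interferon-stimulated list (60 peaks) and at all other risen peaks (2034). The list's medians are 1.389 and 1.439 in control clones and 1.853 and 1.585 in IRF1-guide clones, and those of the other peaks are 1.487, 1.407, 1.089 and 0.906 in the same order.

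Without hIFNb, interferon-stimulated genes carried less H3K27ac in IRF1-guide clones than in control clones as a list, while no single peak passed the test. The list's 99 peaks had a median difference of -0.44 (camera adjusted p = 5.18e-11, adjusted p = 0.0752 with an estimated correlation), the MHC list one of -0.26 (adjusted p = 3.80e-05, adjusted p = 0.201 with an estimated correlation), and the GBP and APOL list one of -0.44 (adjusted p = 0.00026, adjusted p = 0.102 with an estimated correlation). Adjusted over the list alone 21, 9 and 7 of their peaks fell. Among the smallest p, none of which passed, were promoters of UBE2L6, the conjugating enzyme of ISG15, with 122.5 ± 13.4 in control and 42.5 ± 2.1 in IRF1-guide clones, of RTP4, with 172.5 ± 36.1 and 56 ± 7.1, and of SLFN12L, with 97 ± 7.1 and 22 ± 5.7 (SD, n = 2; limma, log2 differences of -1.50 ± 0.20, -1.60 ± 0.21 and -2.11 ± 0.26, adjusted p = 0.0532 for each). In the other direction stood a peak inside ELP2, 25.5 ± 4.9 against 134.5 ± 24.7, and one inside NXPH1, 1.5 ± 0.7 against 74.5 ± 47.4 (adjusted p = 0.0532 for both). The IRF1 gene differed by -0.37 ± 0.21 (adjusted p = 0.53). The xenobiotic, steroid and retinoid list was higher in IRF1-guide clones, with a median of 0.185 (camera adjusted p = 0.00738, adjusted p = 0.322 with an estimated correlation), and the high-grade list lower, with a median of -0.28 (adjusted p = 0.0321, adjusted p = 0.322 with an estimated correlation). Neither held without IRF1-guide clone 13 without hIFNb (adjusted p = 0.235 for each), and the latter also failed without control clone 4 without hIFNb (adjusted p = 0.153). Fry gave the xenobiotic list 0.361 and the high-grade list 0.072, promoter peaks alone gave them 0.25 and 0.0572, and links within 200 kb gave the high-grade list 0.321. In all 0 peaks were called by limma, with 3851 at an unadjusted p under 0.05, and 0 by voom. A block by column ending gave 403 calls, a pseudocount of 10 gave 3, no variance trend 6, centring on 10 Mb windows 21, and leaving out IRF1-guide clone 11 without hIFNb 1.

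With hIFNb, IRF1-guide clones had less H3K27ac than control clones at 700 peaks and more at 76, and 6 of the 700 belonged to the GBP and APOL list. A peak linked to GBP7 that covers an end of GBP4 (chromosome 1, 89197716 to 89203274) went from 49.5 ± 10.6 to 175.5 ± 4.9 in control clones and from 12.5 ± 2.1 to 24.5 ± 4.9 in IRF1-guide clones (SD, n = 2). The difference with hIFNb was -2.80 ± 0.29 on the log2 scale (limma, adjusted p = 0.00606). The body of GBP4 (89181144 to 89198942) ends inside this peak, while that of GBP7 (89131742 to 89176003) does not reach it. The link to GBP7 is thus one of distance alone. Whether that end of GBP4 is its TSS was not established, so the peak, not counted as a promoter peak, may be one of GBP4. A peak between GBP5 and GBP6 (89281580 to 89293547) reached 229 ± 21.2 in control and 40.5 ± 4.9 in IRF1-guide clones (-2.47 ± 0.27, adjusted p = 0.00655). The promoter of IL18BP, which encodes a soluble inhibitor of interleukin 18, reached 118 ± 48.1 and 19 ± 1.4 (-2.51 ± 0.37, adjusted p = 0.0111). A peak in APOL3 reached 212.5 ± 2.1 and 58.5 ± 0.7 (-1.84 ± 0.27, adjusted p = 0.0107), and the CXCL10 promoter 375 ± 19.8 and 126 ± 49.5 (-1.62 ± 0.34, adjusted p = 0.0371). In the GBP and APOL list 6 peaks at 5 genes were lower and 0 higher (20 lower and 2 higher adjusted over the list alone; median -0.59, camera adjusted p = 3.71e-06, adjusted p = 0.0878 with an estimated correlation). The GBP1 promoter, chosen after its values were seen, had 424.5 ± 29 and 200.5 ± 34.6 (adjusted p = 0.0548). Without control clone 1 or 4 with hIFNb the adjusted p was 0.0979 and 0.0817 at both the GBP7 and GBP5 peaks, 0.119 and 0.0817 at IL18BP, 0.115 and 0.0843 at APOL3, and 0.205 and 0.157 at CXCL10. Without IRF1-guide clone 11 or 13 with hIFNb it was 0.0571 and 0.0582 at IL18BP, 0.0544 and 0.0606 at APOL3, and 0.0544 and 0.26 at CXCL10.

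**Figure D3:**
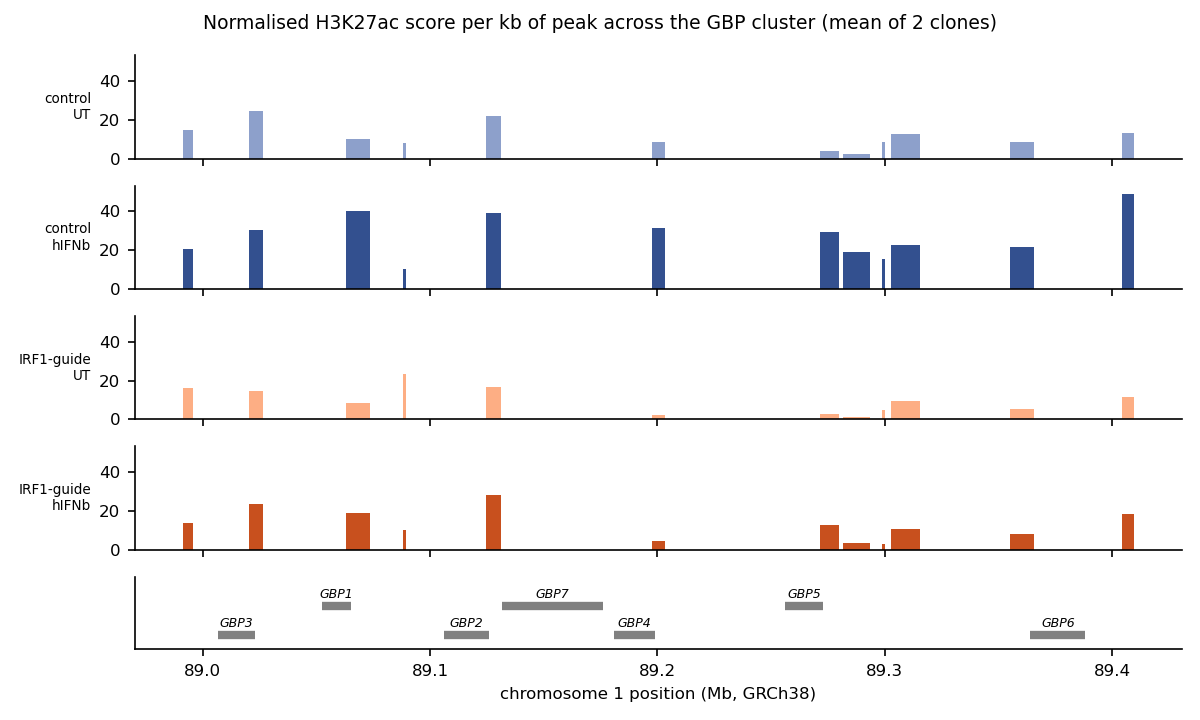
Mean H3K27ac score per kb of peak (y axis, from 0; mean of 2 clones) of the 12 peaks of the guanylate-binding protein cluster on chromosome 1 (x axis, position on GRCh38), in the 4 groups, with gene bodies drawn below. The peak at 89281580 to 89293547 holds 19.1 per kb in control clones and 3.38 per kb in IRF1-guide clones with hIFNb.

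No difference with hIFNb was called at the promoters of IRF9, with 337 ± 49.5 in control and 339.5 ± 9.2 in IRF1-guide clones (limma, log2 difference 0.02 ± 0.22, adjusted p = 0.979), and ISG15, with 1034.5 ± 68.6 and 1034.5 ± 211.4 (-0.01 ± 0.20, adjusted p = 0.982). With SE of 0.20 to 0.22, small differences were not detectable. Nor was one called at the promoters of RTP4, with 430 ± 42.4 and 259 ± 9.9 (-0.73 ± 0.21, adjusted p = 0.11), UBE2L6, with 353.5 ± 38.9 and 221 ± 18.4 (-0.67 ± 0.20, adjusted p = 0.12), or RSAD2, with 391.5 ± 6.4 and 275 ± 9.9 (-0.51 ± 0.28, adjusted p = 0.403), chosen after their values were seen. The interferon-stimulated list as a whole had 4 lower peaks, at CXCL10 and linked to CXCL11, SAMD9L and RSAD2, and 4 adjusted over the list alone (median -0.18, camera adjusted p = 0.0446, adjusted p = 0.369 with an estimated correlation). It was not called without control clone 1 with hIFNb (adjusted p = 0.318), without IRF1-guide clone 13 with hIFNb (adjusted p = 0.144), or with median-of-ratios scaling (adjusted p = 0.0537), quantile scaling (adjusted p = 0.0634), a minimum mean of 20 (adjusted p = 0.051), links within 200 kb (adjusted p = 0.127) or promoter peaks alone (adjusted p = 0.092). The MHC list had 0 called peaks and 2 lower adjusted over the list alone (median -0.29, camera adjusted p = 0.000841, adjusted p = 0.369 with an estimated correlation, and 0.0734 without IRF1-guide clone 13 with hIFNb). Of metabolic genes, a peak inside ACSL4, a long-chain acyl-CoA synthetase gene, had 247 ± 18.4 in control and 93.5 ± 7.8 in IRF1-guide clones (-1.39 ± 0.21, adjusted p = 0.0113). A peak linked to ALDH1A1, a retinaldehyde dehydrogenase gene, was higher, 63 ± 8.5 and 127.5 ± 17.7 (1.01 ± 0.22, adjusted p = 0.0432). It was the only called peak of the xenobiotic, steroid and retinoid list, which was higher as a whole (median 0.35, camera adjusted p = 0.000841, adjusted p = 0.369 with an estimated correlation; fry 0.147, promoter peaks alone 0.372, and 0.127 by camera without IRF1-guide clone 13 with hIFNb). The SNAI1-linked peak was higher, 120 ± 9.9 and 270 ± 7.1 (1.17 ± 0.21, adjusted p = 0.0209), and single peaks linked to CTSE, HMGA2 and GCG were lower by -2.22 ± 0.48, -2.17 ± 0.46 and -2.37 ± 0.32 (adjusted p = 0.0424, 0.0392 and 0.00924). The ALDH1A1 call was lost whichever of the 8 libraries was left out (0.0576 to 0.276), and those at SAMD9L (0.0784 to 0.18), RSAD2 (0.0991 to 0.144), ACSL4 (0.0514 to 0.113) and SNAI1 (0.0966 to 0.129) whichever of the 4 hIFNb libraries was left out. The CXCL11 (0.0653 to 0.214) and CTSE (0.0623 to 0.198) calls were lost with each of these 4, or either control library without hIFNb, left out. The HMGA2 call was lost with each control library, or either library of IRF1-guide clone 11, left out (0.0502 to 0.186), and the GCG call without either control clone (0.113 and 0.0843) or clone 13 (0.0546) with hIFNb.

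Of the 700 peaks lower with hIFNb in IRF1-guide clones 651 were not promoter peaks, against 23181 of all 31961. Of the 700, 356 (50.9%) had risen with hIFNb over all clones, against 45.9 if the sets were independent, and 344 had not. The selection on the response over all clones has no covariance with the genotype difference in the model. Both tests use the same variance estimate of a peak, however, so their calls can coincide more often than independent sets would. Of the 824 peaks that fell over all clones 2 were among the 700, against 18 if independent. At the 700 the median difference was -2.05 with hIFNb and -0.855 without. The largest was at chromosome 5, 153349090 to 153355588, with a mean score of 102.5 in control and 1.5 in IRF1-guide clones (n = 2, -5.29 ± 0.91, limma, adjusted p = 0.0176). A peak in PTPRT had 38 and 0.5 (-4.78 ± 0.65, adjusted p = 0.00924). The largest rises included the PDE3A promoter, 2 ± 1.4 in control and 24.5 ± 3.5 in IRF1-guide clones (3.17 ± 0.57, adjusted p = 0.0217). The 776 calls were without overlap, as were 43.9% of all peaks. No call was left by limma without control clone 1 or control clone 4 with hIFNb, and the count was 168 and 130 without IRF1-guide clones 11 and 13 with hIFNb. The chromosome 5 peak (0.0651 to 0.162) and PDE3A (0.0812 to 0.15) were not called whichever of these 4 was left out, and PTPRT had an adjusted p of 0.115 and 0.0843 without control clones 1 and 4. A pseudocount of 10 gave 1418 and a block by column ending 1904. The lower share was 90.2% as deposited and 80% after centring on 10 Mb windows, where the CXCL10 and CXCL11 calls ended.

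Over both treatments, with the clone as the unit (2 against 2), 146 peaks were lower and 19 higher in IRF1-guide clones. The GBP7-linked peak (-2.35 ± 0.27, limma, adjusted p = 0.0366), the GBP5-linked peak (-1.73 ± 0.26, adjusted p = 0.0372) and APOL3 (-1.53 ± 0.23, adjusted p = 0.0402) were the 3 called peaks of the GBP and APOL list, which had 16 lower adjusted over the list alone. The largest fall was near OR4C6, an olfactory receptor gene, -4.44 ± 0.69 (adjusted p = 0.041), and a peak in PTPRT differed by -3.99 ± 0.50 (adjusted p = 0.0366). Among the rises, NXPH1 differed by 3.88 ± 0.55 (adjusted p = 0.0366), ELP2 by 2.36 ± 0.26 (adjusted p = 0.0366) and the promoter of GLI2, a transcription factor of Hedgehog signalling, by 1.94 ± 0.29 (adjusted p = 0.0398). Of the 146 lower peaks 97 (66.4%) had risen with hIFNb, against 9.6 if independent. The GBP and APOL list had a median of -0.55 and the interferon-stimulated list one of -0.31 (camera adjusted p = 3.32e-06 for both), the MHC list one of -0.30 (adjusted p = 6.44e-05; all 3 adjusted p = 0.383 with an estimated correlation), with 10 lower and 1 higher and 5 lower adjusted over the list alone in the latter pair. The xenobiotic list was higher (median 0.27, camera adjusted p = 0.000282) and the high-grade list lower (median -0.30, adjusted p = 0.039; both adjusted p = 0.556 with an estimated correlation). Without clone 13 they had an adjusted p of 0.114 and 0.2, and without clone 4 the high-grade list had 0.179. Fry gave them 0.366 and 0.238, and promoter peaks alone 0.303 and 0.324. The high-grade list had 0.371 with links within 200 kb and 0.0901 with a minimum mean of 20. With each of the 4 clones left out in turn limma called 0 peaks (at the GBP7 peak the adjusted p was 0.416, 0.309, 0.159 and 0.274 without clones 1, 4, 11 and 13), against 4689 of the 31961 at an unadjusted p under 0.05 with all 4. It called 0 with a minimum mean of 20, 2 without a variance trend, 321 with 10 Mb centring and 495 with a pseudocount of 10. With the 8 libraries in place of clone means it called 732 with a correlation within clones and 1954 as independent. In 130 of the 165 called peaks the libraries of the genotypes did not overlap, against 8.9% of all peaks.

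Clones of the same genotype also differed from each other. In a model with the clone as a factor 3990 peaks differed between control clones 1 and 4, and 4151 between IRF1-guide clones 11 and 13. The column names of clones 1 and 11 end in R1 and those of clones 4 and 13 in R2, so differences between clones of a genotype cannot be told apart from differences between these endings. The mean of the IRF1-guide clones differed from that of the control clones at 9279 peaks. That fit takes no account of the spread between clones, and in simulated data it made 2907 false calls where clone means made 6. The SD of the log2 differences was taken at peaks with a mean score of at least 100. It was 0.366 between the control clones, 0.375 between the IRF1-guide clones and 0.356 between genotypes. The genotype difference is between means over clones, which averages out part of the spread between clones. The others compare individual clones, so these SDs do not show whether genotypes differed more or less than clones. Chromosome 7 stood higher in control clone 1 than in clone 4 by a median of 0.423, with 406 of its 1630 peaks higher and 20 lower, and chromosome 20 higher in IRF1-guide clone 11 than in clone 13 by 0.346, with 230 of 915 higher and 13 lower. Between genotypes the medians reached 0.175 on chromosome 1 and -0.159 on chromosome 20. Medians of 288 windows of 10 Mb had an SD of 0.127 between genotypes, 0.185 between the control clones and 0.145 between the IRF1-guide clones. With peaks shuffled the mean SDs were 0.05, 0.053 and 0.054. The window SD between genotypes again rests on clone means, so it is not comparable with those between individual clones. The hIFNb response over all clones, which compares each clone with itself, had an SD of 0.139, against 0.058 shuffled. An excess over shuffling therefore does not by itself show a difference in copy number between clones.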

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

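The tests of weaker enrichment, regional differences, correlated peaks, and clone splits of the response at risen peaks were chosen after the results were seen.

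The hIFNb response differed between genotypes in 5 results. The interferon-stimulated list had a larger response in IRF1-guide clones (camera adjusted p = 4.65e-05, adjusted p = 0.299 with an estimated correlation). With the clone as a block the GBP and APOL list had a smaller response (adjusted p = 0.0289, adjusted p = 0.434 with an estimated correlation), and glycolysis (adjusted p = 0.0488, adjusted p = 0.506 with an estimated correlation) and the low-grade epithelial list (adjusted p = 0.0289, adjusted p = 0.434 with an estimated correlation) less negative ones. Without the block these 3 lists did not pass (adjusted p = 0.0845, 0.0845 and 0.0872). With the block 244 single peaks also differed in response, and 0 by limma without it (1258 at an unadjusted p under 0.05, and 0 by voom). Groups of 2 libraries allow no test for a library that stands apart.

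Risen peaks as a whole responded less in IRF1-guide clones, by a median of -0.343 on the log2 scale. The 824 fallen peaks also fell less there, by a median of 0.176, with a smaller response at 72.6% of them. A uniformly weaker enrichment in the treated IRF1-guide libraries would, other things equal, lower the response of every risen set. The 60 risen peaks of the interferon-stimulated list had a median difference of 0.472 (quartiles 0.093 to 0.714), against -0.36 (quartiles -0.872 to 0.05) at the 2034 others. The whole list, however, was already lower in IRF1-guide clones without hIFNb, by a median of -0.44. A set that starts lower can rise more on the log2 scale even in weaker libraries, so this test cannot decide on weaker enrichment. Quantile scaling left 69.3% of risen peaks with a smaller response, against 70.1% as deposited, which argues against the scaling of the values. Low scores remain open as part of the pattern: at the 581 risen peaks with a mean of at least 100 the share was 58.5% and the median -0.08. Clonal variation cannot be told apart from a change that follows the IRF1 guide, since 1 of the 3 splits of 4 clones, the real one (-0.343, highest other 0.107), was as large and 3 splits are too few to give a share under 0.05.

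Of the 700 peaks lower in IRF1-guide clones with hIFNb 344 had not risen with hIFNb, and the median difference at the 700 was already -0.855 without hIFNb. Copy number or other regional differences would not by themselves select peaks that hIFNb raises. Of the lower peaks 50.9% had risen, against 6.55% of all peaks, which argues against such differences as the whole cause. It leaves them open at the 344 that had not risen. After centring on 10 Mb windows 573 of the 700 calls (81.9%) were kept. Centring removes only shifts shared across a window, so it cannot decide on differences narrower than that. With quantile scaling 83% of the calls were lower, against 90.2% as deposited, which argues against the scaling as the cause. Clonal variation cannot be told apart from an effect of the guide: 1 of 3 splits of the clones, the real one, gave as many calls (776, highest other 0), and 3 splits are too few to give a share under 0.05.

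The larger response of the interferon-stimulated list in IRF1-guide clones could come from low scores, but a pseudocount of 10 left a median difference of 0.238, against 0.313, which argues against that. Relative to control clones the list had a median difference of -0.44 without hIFNb and -0.18 with it. The larger response was thus a rise from a lower start, and by its median the list did not end above control clones. Correlation among the list's peaks may account for the small p-value: with an estimated correlation the adjusted p was 0.299. Clonal variation again cannot be told apart, with 1 of 3 splits as large (0.313, highest other 0.032) and too few splits for a share under 0.05.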

How the results depend on the processing

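The voom fit, the column-ending block and the link to every gene with a TSS inside a peak were chosen after seeing the data. Of the single peaks named as called, 2877 values under the alternatives kept their direction and call, 804 kept the direction and lost the call, and none reversed. Several alternatives, such as robust moderation and the clone as a block, leave the log2 change as it is and could not reverse it. Nor could leaving out a library where the groups did not overlap. For called lists the counts were 364, 52 and 0. The cause was not tested for any change below except where fewer libraries were fitted. With the clone as a block the calls were 10363 over all clones, 7867 in control clones, 4502 in IRF1-guide clones and 244 for the difference in response. With the column-ending block they were 5181, 2992 and 767 for the responses, 403 for the genotypes without hIFNb and 1904 with it. That ending gave correlations of 0.06 to 0.104 between libraries of different genotypes. The 4 compared libraries alone gave 917 in control and 41 in IRF1-guide clones, with fewer degrees of freedom. A minimum log2 change of 1 gave 1586 over all clones. A pseudocount of 10 gave 3 between genotypes without hIFNb, 1418 with it and 495 over both treatments. Without a variance trend these were 6 without hIFNb and 2 over both treatments, and with 10 Mb centring 21 and 321. Over both treatments a minimum mean of 20 gave 0, a correlation within clones 732 and independent libraries 1954. List calls went from 25 of 16 lists in 7 comparisons to 6 with an estimated correlation. The correlation of responses at peaks called for their average moved from 0.822 to 0.856 with a minimum mean of 20, and the SD of window medians from 0.127 to 0.103 with a pseudocount of 10. Leaving out 1 library gave 1426 to 2111 over all clones, 206 to 1489 in control clones, 44 to 339 in IRF1-guide clones, 0 for the difference, 0 to 1 between genotypes without hIFNb and 0 to 851 with it, and leaving out 1 clone gave 0 over both treatments; a group left with 1 library is assumed to vary like the others. Calls between clones of a genotype, summed over both genotypes, numbered 8141 in the main fit and stayed between 7847 and 8731. Motif tests and tests on deposited read counts were not run. The called share was 5.54% at means under 10 and 12.8% over 200 for hIFNb over all clones. Between genotypes with hIFNb it was 1.7% at means under 10, 2.97% at means of 10 to 20 and 1.86% over 200. Whether depth sets these shares was not tested.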

Other observations

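The test by splits of the 4 clones was chosen after its result was seen, and the other tests in this part before theirs. The gene-body test was prompted by a fall already seen at RIGI, and that peak is among those it counts.

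The peak that fell in the body of RIGI, whose promoter rose, raised the hypothesis that H3K27ac falls in the bodies of genes whose promoter rises. Of 342 peaks other than promoter peaks in the bodies of the 485 genes with a risen promoter, 9 (2.63%) fell and 54 (15.8%) rose, and of 6866 such peaks in other genes 155 (2.26%) fell and 444 (6.47%) rose. A one-sided Fisher exact test gave p = 0.376 for more falls, so the hypothesis was not borne out.

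In a model of the split alone, 1 of the 35 splits of the 8 libraries into 4 and 4, the split by hIFNb, called as many as 1311 peaks, and the highest other, the split by genotype, called 427. That excludes a chance division only if the 8 libraries are taken as unpaired. They are paired by clone, and the 8 splits that part the libraries of every clone are too few for a share under 0.05 (1311, highest other 0). For the comparison over both treatments 1 of 3 splits of the clones gave as many calls (165, highest other 0), too few splits for a share under 0.05.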
